A study of Mus musculus with 6 samples.

How the data were processed

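RNA sequencing was carried out on 6 libraries of total RNA from cultured mouse cells. According to the labels, mesenchymal stromal cells (MSCs, the plastic-adherent stromal cells of bone marrow) were obtained by digesting whole bone marrow of CB6F1 mice, an F1 hybrid laboratory strain, with acute graft-versus-host disease (aGVHD, in which transplanted donor immune cells attack the recipient's tissues). The cells were grown in high-glucose DMEM with serum and antibiotics. They were then treated in culture with a compound labelled only R (0.5 um, with the unit as labelled) or with its vehicle, DMSO. Each group had 3 libraries. What R is and for how long the cells were treated are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

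The values are FPKM (fragments per kilobase of gene, scaled to the counted reads of the library), which the authors computed before they deposited one table of all genes and samples. Per the submitters' processing notes, the genome build was GRCm38 (mm10) and edgeR 3.18.1 was used. The aligner, the read counter, the gene annotation, the strandedness of the libraries and the read length are not given in the sources used here. The table listed 49328 genes by Ensembl identifier, and its final line broke off after 10 characters of an identifier. The last 21929 complete lines held 0 in every library. Of the 55450 genes of the reference annotation, GENCODE M21 on GRCm38, 6169 were not analysed here, among them 906 protein-coding genes. Most of these lie on chromosomes 12, 15, 16, 17, 18, 19 and Y. Symbols were found for 49281 of the listed identifiers and not for 47. Symbols, biotypes, coordinates and exon lengths came from the reference annotation.

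FPKM are not counts, but the depth could be estimated from them. Multiplied by the summed exon length of its gene, a low value was a whole multiple of the value of 1 read. At a tolerance of 0.02 reads, this held for 98.3% to 98.4% of the values under 20.5 reads in each library. The estimated depth was 21750000, 17980000 and 18070000 reads in R replicates 1, 2 and 3. It was 17070000, 18740000 and 20010000 reads in vehicle replicates 1, 2 and 3. A gene of 1 kb with 3 reads would have an FPKM of 0.138 to 0.176, depending on the library. These read numbers cover counting error only and depend on the exon lengths of the reference annotation, which may not be the one the authors used.

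Values were tested as log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, with a linear model of the 2 groups, empirical Bayes moderation with a trend in the prior variance and equal weights. Genes were kept if they had an FPKM of at least 1 in at least 3 of the 6 libraries, which left 11862. Adjusted p-values are Benjamini-Hochberg values over the kept genes, and the threshold was 0.05. A log2 change is R minus vehicle on the log2(FPKM + 1) scale, which understates the change of genes with low values. Its error is the moderated standard error (SE). Levels are group means of FPKM ± SD with n = 3. The test was checked on simulated reads for 11853 genes, drawn around the vehicle means at the estimated depths with a dispersion of 0.02. With 50 genes changed at each size, it recovered 32% of 1.5-fold changes, 86% of 2-fold, 96% of 4-fold and 100% of 8-fold changes. Of its 174 calls in that simulation, 17 were false, a share of 9.77%, so that the adjusted p-values were somewhat too small there. The same dispersion was set for every gene and was not estimated from these libraries, so the recovery may be lower for genes that vary more.

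A set of 44 gene lists (pathways, lineages and markers of other cell types) was fixed before the data were examined. The 38 lists with at least 5 kept members were tested with camera from limma, which compares a list with all other genes, at a preset correlation of 0.01 between genes and with adjustment over the 38 lists. Camera with a correlation estimated from the residuals and the directional fry test were run beside it. With an estimated correlation camera uses the residual degrees of freedom of the 6 libraries, and with a preset one far more. A call lost with an estimated correlation therefore need not reflect correlation between genes. Members past the threshold were counted after adjustment over all kept genes and again after the adjustment was restricted to the list. The genes named in the text follow a rule that was also fixed beforehand. Among the genes past the threshold with a mean of at least 5 FPKM in one group and no overlap between the groups, it takes the 12 largest rises and the 12 largest falls, without predicted gene models. From each list it takes up to 4 kept members with the smallest p-values, and every kept member of the JAK, STAT and SOCS family. Other genes named were chosen after their values were seen, most of them as further members of a list.

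The labels do not say whether replicates came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical. The alternatives tried were other pseudocounts, filters and scalings, limma without the trend, array weights, a replicate block, the omission of each library in turn and, chosen after seeing the data, limma-voom on the recovered reads. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. The table had 0 columns of values beyond those of the 6 libraries.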

Results

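Gene expression was measured by RNA sequencing in bone marrow MSC cultures from mice with aGVHD, 3 treated in culture with the compound labelled R and 3 with its vehicle. The estimated depth was 17070000 to 21750000 reads per library, and 11862 genes were high enough to be tested. The question put to the data was which transcripts differed between R-treated cells and their vehicle controls. The libraries correlated more closely within a group (Pearson's r of 0.977 to 0.986 across genes, which are not independent replicates) than between groups (0.936 to 0.963). The first principal component held 59.6% of the variance and separated the groups, and the second held 13.2%. Transcripts of macrophages, the phagocytes that often persist in marrow cultures, were abundant in both groups. Lyz2, which encodes macrophage lysozyme, ranked first or second among all kept genes in each library, with 11100 ± 1590 FPKM in vehicle and 9450 ± 1170 FPKM in R (SD, n = 3; log2 change -0.23, SE 0.19, adjusted p = 0.54).

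Cells treated with R had far lower levels of interferon-induced and antigen-presentation genes, and higher levels of a smaller set of genes, among them matrix and growth factor genes. The deepest fall was that of Iigp1, an interferon-inducible GTPase of pathogen defence (chromosome 18, 60376027 to 60392634, GRCm38), from 101 ± 28.8 to 0.434 ± 0.146 FPKM (log2 change -6.11, SE 0.22, adjusted p = 5.5e-05). Acod1, which makes itaconate in activated macrophages, fell from 83.6 ± 22.2 to 1.65 ± 0.441 FPKM (log2 change -4.98, SE 0.2). Among the rises, Hbegf, which encodes a secreted growth factor of the EGF family, went from 8.9 ± 1.73 to 26.4 ± 5.08 FPKM (log2 change 1.46, adjusted p = 0.0047). The basic fibroblast growth factor Fgf2 rose from 5.7 ± 2.09 to 18.2 ± 1.87 FPKM (log2 change 1.56, adjusted p = 0.0071).

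In all, 809 genes passed an adjusted p of 0.05 in limma, 284 higher and 525 lower in R. A log2 change of at least 1 in size was reached by 305 of them, 59 higher and 246 lower. In each of the 809 the 3 values of one group all lay above those of the other, as they did in 29.3% of all kept genes, where chance gives 10%. The count fell to 425, 422 and 506 without R replicate 1, 2 and 3 and to 337 and 385 without vehicle replicates 1 and 2, and it was 879 without vehicle replicate 3. Whichever library was left out, 236 of the 525 falls and 37 of the 284 rises were called.

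**Figure D1:**
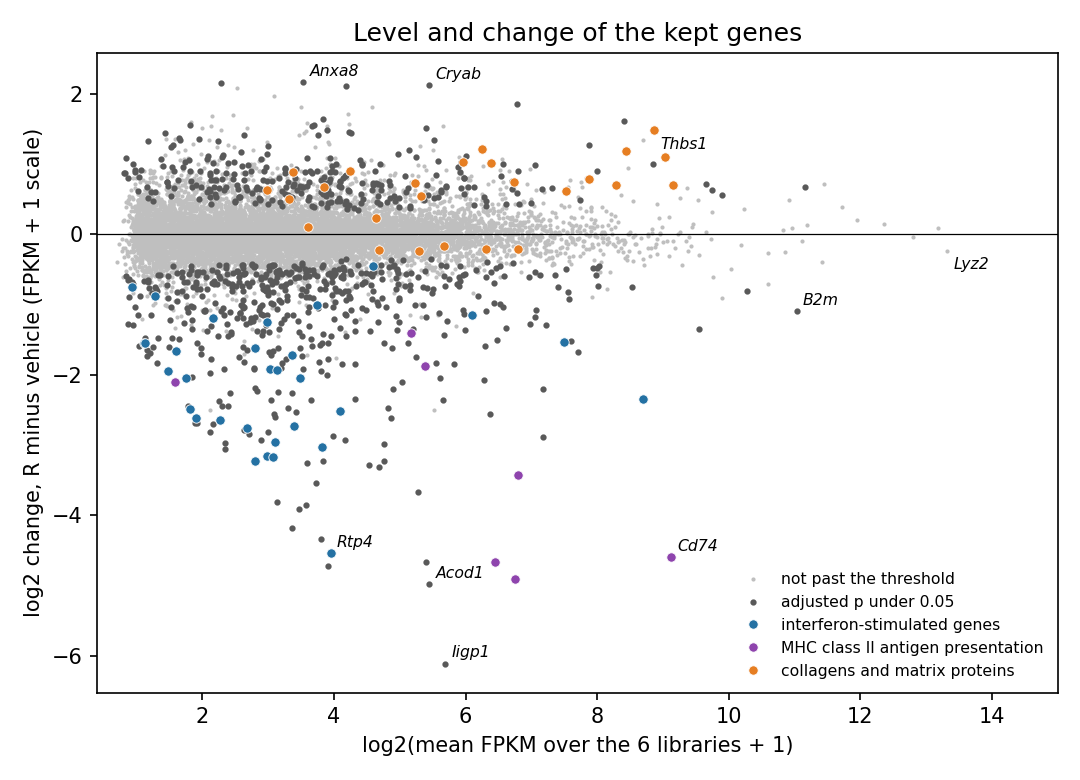
Level against change for the 11862 kept genes: the horizontal axis is the log2 of the mean FPKM of the 6 libraries plus 1, and the vertical axis the log2 change, R minus vehicle. Each point is a gene, with darker points past the threshold and 3 lists in colour; Iigp1 lies lowest at -6.11, and no called rise exceeds 2.17.

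The 12 largest falls were Iigp1, Acod1, H2-Eb1, Cxcl9, Gbp2, H2-Aa, Cd74, Rtp4, Tgtp2, Serpina3g, Cxcl10 and Mir5107. Their log2 changes ran from -6.11 to -3.85. Rtp4, a chaperone of receptor transport that interferon induces, fell from 28.6 ± 5.9 to 0.26 ± 0.00102 FPKM. Serpina3g, a serine protease inhibitor of activated leukocytes, fell from 18.5 ± 6.03 to 0.0379 ± 0.0448 FPKM, which stands for 0 to 4 reads in an R library. Mir5107 is an 88-nucleotide microRNA gene (chromosome 18, 60812076 to 60812163) that lies on the same strand within Cd74 (60803848 to 60812652), so its reads may belong to Cd74 and its value is uncertain. The 12 largest rises had log2 changes from 2.17 to 1.46, and Anxa8, Cryab, Igfbp5, Nqo1, Fgf2, Pdlim1, Thbs1, Prss23 and Hbegf were among them. Cryab, a small heat shock protein, rose from 14.6 ± 2.87 to 70.2 ± 29.6 FPKM. The 12 falls kept their call under each alternative tried, and so did the rises of Cryab, Fgf2 and Hbegf. The calls of Anxa8 and Nqo1 ended without R replicate 2 (adjusted p = 0.0502 and 0.0501) and without a filter on low values. Those of Igfbp5, Pdlim1, Thbs1 and Prss23 ended without R replicate 2 or vehicle replicate 1 (adjusted p up to 0.14, 0.12, 0.12 and 0.14), without R replicate 1 for all but Igfbp5, without R replicate 3 for all but Prss23, without vehicle replicate 3 for all but Igfbp5 and without vehicle replicate 2 for Igfbp5. All 4 also ended without a filter on low values (adjusted p = 0.12 to 0.13), and that of Igfbp5 with a pseudocount of 5 (adjusted p = 0.058).

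Interferon-stimulated genes fell almost as a whole in R. Of 31 kept members, 30 fell, 0 rose and 1 did not pass, and 31 fell when adjusted over the list alone. Besides Rtp4, Oas3, which senses double-stranded RNA, fell from 14.2 ± 1.77 to 0.968 ± 0.213 FPKM, and Zbp1, a sensor of Z-form nucleic acids, from 11.6 ± 2 to 0.339 ± 0.128 FPKM. Ifitm3, an antiviral membrane protein and the most abundant member, fell from 693 ± 133 to 137 ± 32.5 FPKM. The list median was -1.94 (camera, adjusted p = 6.5e-40). The GTPases and other genes that interferon-gamma induces fell further. Of 22 kept members 21 fell, with a list median of -2.65 (camera, adjusted p = 2.0e-31), and 22 did so when adjusted over the list alone. Gbp2, a guanylate-binding protein, fell from 80.2 ± 21.1 to 2.19 ± 0.82 FPKM. The T-cell-attracting chemokines Cxcl9 and Cxcl10 are neighbours on chromosome 5 (92321347 to 92328079 and 92346638 to 92348889). Cxcl9 fell from 28 ± 7.28 to 0.0797 ± 0.0745 FPKM, or 0 to 8 reads per R library, and Cxcl10 from 19.7 ± 2.25 to 0.38 ± 0.207 FPKM. With an estimated correlation each of these list calls was lost (adjusted p = 0.19 for both), while fry gave an adjusted p of 0.0013 for both. Whichever library was left out, 28 of the 30 and each of the 21 falls were called; the others were Herc6, called in 3 of the 6 fits, and Oas1b, called in 1.

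The antigen-presentation genes fell with them. Each of the 20 kept MHC class I genes, which present peptides to CD8 T cells, was lower in R, over all genes and when adjusted over the list alone. Tap1, the peptide transporter, fell from 52.3 ± 9.88 to 11.4 ± 1.64 FPKM, and Nlrc5, the transcriptional activator of the class I genes, from 13.5 ± 2.65 to 2.84 ± 0.225 FPKM. B2m, the common light chain, was among the most abundant transcripts and fell from 2860 ± 377 to 1340 ± 214 FPKM. Each of the 7 kept MHC class II genes fell as well, over all genes and when adjusted over the list alone. H2-Ab1, H2-Aa and H2-Eb1, which lie side by side on chromosome 17 (34257689 to 34316674), fell from 203 ± 86.5, 167 ± 72.2 and 207 ± 101 FPKM to 17.1 ± 5.08, 5.55 ± 2.62 and 5.82 ± 3.36 FPKM. Cd74, the invariant chain, fell from 1070 ± 459 to 43.8 ± 21.4 FPKM (log2 change -4.6, SE 0.47, adjusted p = 0.0024). The list medians were -1.54 for class I (camera, adjusted p = 1.7e-23) and -3.43 for class II (camera, adjusted p = 3.3e-09). With an estimated correlation both calls were lost (adjusted p = 0.21 and 0.22). Whichever library was left out, 17 of the 20 class I falls and 6 of the 7 class II falls were called. Among the others, the call of B2m ended without vehicle replicate 1 or 2 (adjusted p = 0.062 for each). The class I genes of the H2-Q and H2-T groups are near-identical copies whose reads may be shared, so that the values of H2-Q6 (41 ± 13.1 to 3.26 ± 1.08 FPKM) and its relatives are uncertain.

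**Figure D2:**
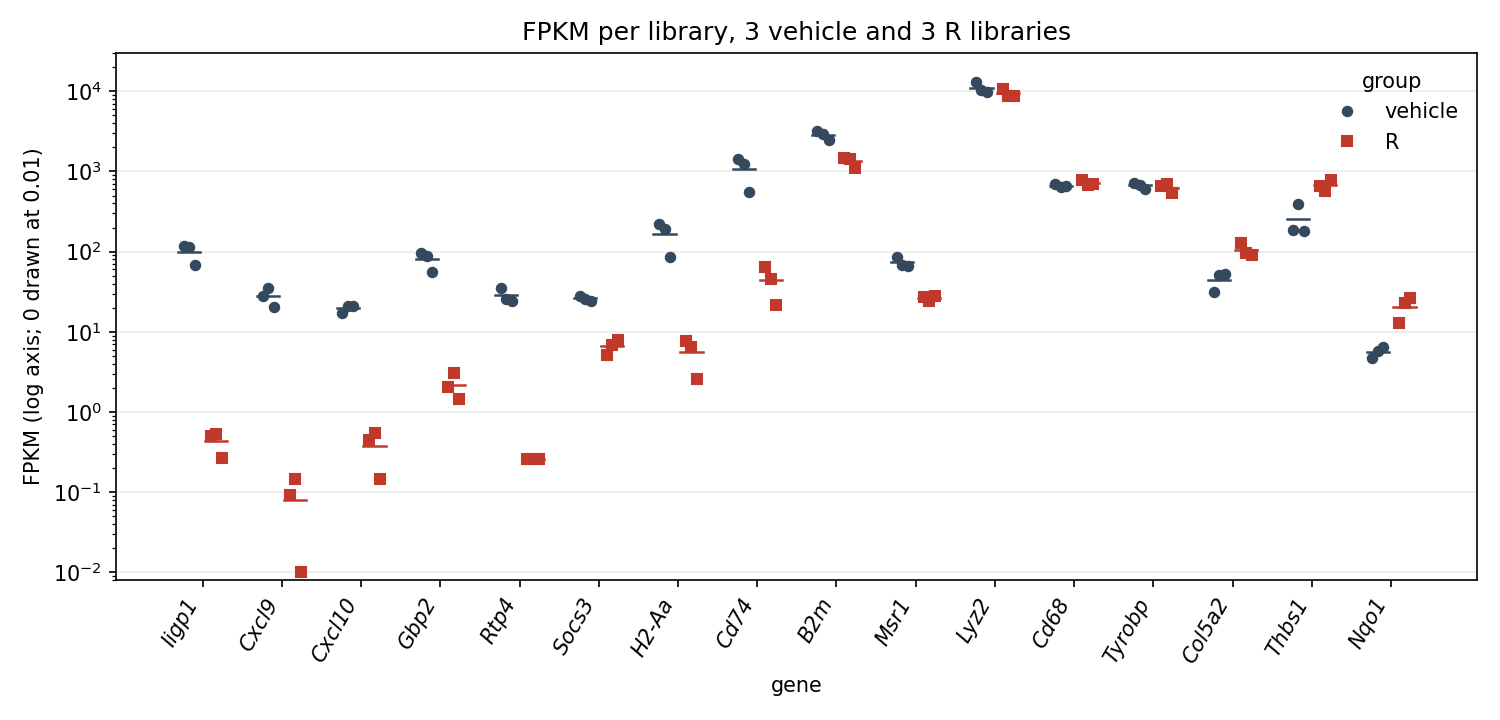
FPKM of 16 genes in each library on a log axis, with vehicle libraries as circles, R libraries as squares and group means as short lines. The R libraries lie below the vehicle libraries for the 10 genes from Iigp1 to Msr1, the groups overlap for Lyz2, Cd68 and Tyrobp, and the R libraries lie above for the 3 genes from Col5a2 to Nqo1.

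Among the JAK kinases, the STAT factors they activate and the SOCS proteins that restrain them, 7 of 17 kept genes fell and 0 rose. Stat2 fell from 14.8 ± 4.36 to 3.69 ± 0.405 FPKM. Stat3 fell from 22.5 ± 0.0935 to 12.6 ± 1.2 FPKM. The feedback inhibitors Socs1 (5.81 ± 1.14 to 0.972 ± 0.121 FPKM) and Socs3 (26.1 ± 1.83 to 6.64 ± 1.46 FPKM) fell too. Stat5a and Jak3 fell by 0.42 and 0.53 on the log2 scale, and these 2 calls were lost without each library other than vehicle replicate 3 (adjusted p up to 0.14 and 0.16). Both also ended without the filter on low values (adjusted p = 0.077 and 0.12), and that of Jak3 ended with pseudocount 5 (adjusted p = 0.052), quantile normalization (adjusted p = 0.057) and equal medians (adjusted p = 0.052). The other 10 did not pass: the log2 changes were -0.35 for Jak1, -0.27 for Jak2, -0.31 for Tyk2, -0.16 for Stat6, -0.09 for Stat5b, -0.25 for Socs2, -0.17 for Socs4, 0.34 for Socs5, -0.01 for Socs6 and -0.04 for Socs7. The value of Socs6 changed sign under several scalings, that of Socs7 was 0 without R replicate 2, and Jak2 passed without R replicate 3 (adjusted p = 0.049). A total of 8 fell and 1 rose when adjusted over the list alone, and the list median was -0.31 (camera, adjusted p = 3.2e-06, or adjusted p = 0.26 with an estimated correlation).

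STAT3 and STAT5 target genes, cytokines and NF-kappaB targets went down in part. Of 16 STAT3 and STAT5 targets 7 fell, among them the oncostatin M receptor Osmr (3.63 ± 0.458 to 0.938 ± 0.191 FPKM) and Fgl2 (27.1 ± 11.2 to 2.64 ± 0.668 FPKM). Of 20 kept cytokines and chemokines 10 fell and 0 rose. Ccl2, which draws monocytes, fell from 319 ± 73.6 to 99.8 ± 28.6 FPKM, and Ccl5, which draws T cells, from 17.3 ± 4.68 to 2.21 ± 0.97 FPKM. Of 16 NF-kappaB feedback and target genes 6 fell, with the adhesion molecule Icam1 (27.7 ± 3.27 to 10.1 ± 0.475 FPKM) and the costimulatory receptor Cd40 (4.03 ± 0.678 to 1.16 ± 0.291 FPKM) leading. Adjusted over the list alone the counts were 8 falls and 2 rises for the STAT targets, 12 falls and 4 rises for the cytokines and 8 falls and 1 rise for the NF-kappaB genes. The medians were -0.44, -0.88 and -0.29 (camera, adjusted p = 0.0042, 4.3e-06 and 2.5e-05). With an estimated correlation all 3 calls were lost (adjusted p = 0.19 for each). The estimated correlations were -0.03, 0.03 and 0.05, so that high correlation between genes does not account for these losses. Among the STAT targets 4 falls were called without R replicate 1, R replicate 2 or vehicle replicate 2. Of the 10 cytokine and chemokine falls 7 were called whichever library was left out. Among the NF-kappaB genes 4 were called without R replicate 1, 2 or 3 or vehicle replicate 2, and 3 without vehicle replicate 1.

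**Figure D3:**
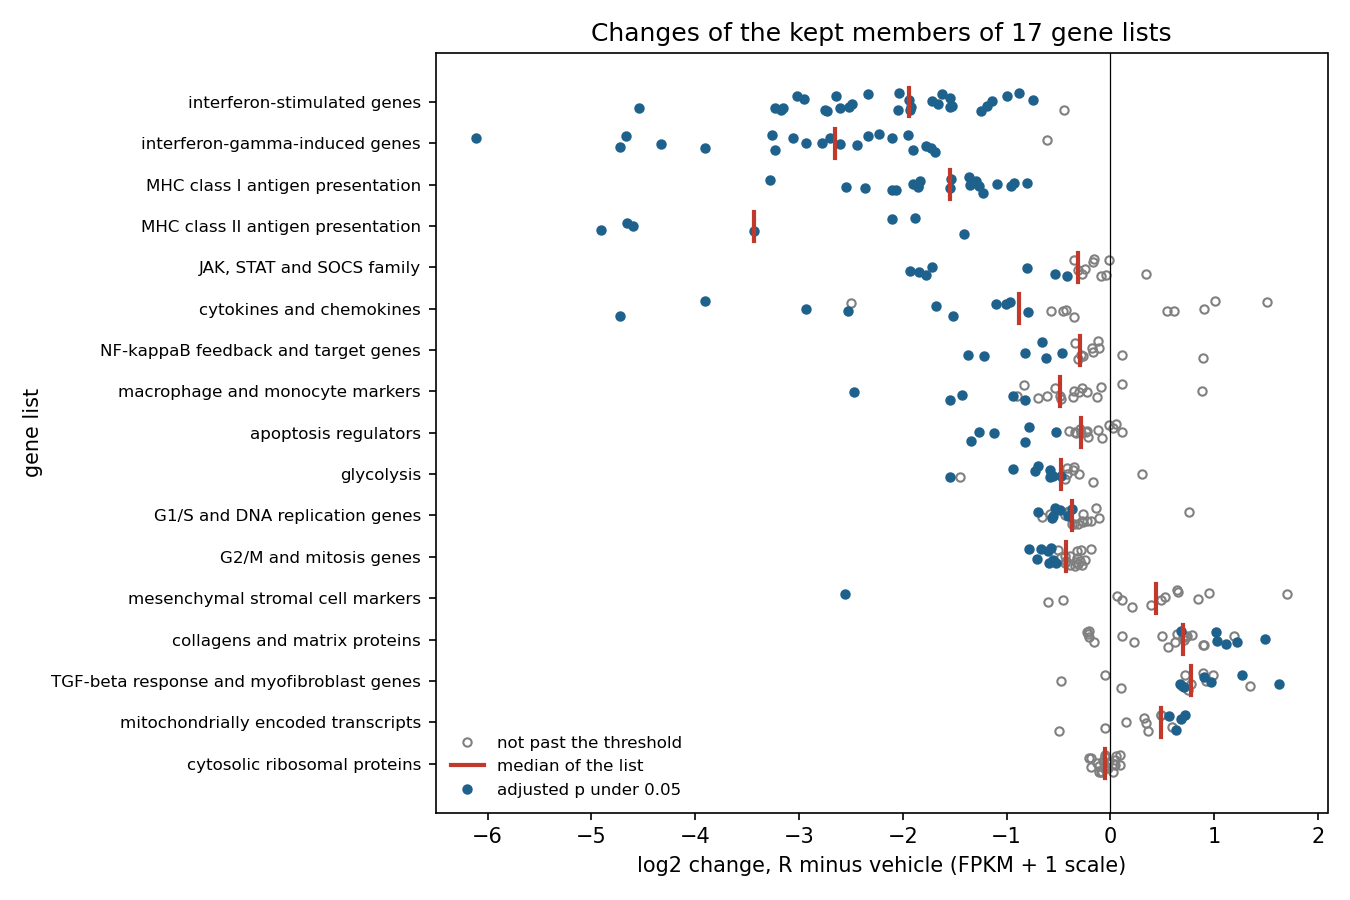
Log2 change, R minus vehicle, of each kept member of 17 gene lists, with filled points past the threshold, open points not past it and a bar at the list median. The medians run from -3.43 for MHC class II genes to 0.78 for TGF-beta response genes, and that of the cytosolic ribosomal proteins is -0.05.

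Most markers of macrophages and monocytes were lower in R, by unlike amounts. Of 21 kept markers 5 fell, 0 rose and 16 did not pass, and 10 fell when adjusted over the list alone. The log2 change was negative in 19 and positive in 2, Cd68 and Cx3cr1 (0.88), and 15 markers had an unadjusted p under 0.05 in limma. Among those that did not pass were C1qa (-0.9), Mrc1 (-0.83) and Adgre1 (-0.53). The high-affinity IgG receptor Fcgr1 fell from 47.3 ± 17.5 to 7.38 ± 0.729 FPKM, the scavenger receptor Msr1 from 73.3 ± 9.91 to 26.5 ± 1.65 FPKM, the integrin Itgam from 23.1 ± 3.74 to 11.4 ± 0.443 FPKM and Aif1 from 39.8 ± 14.5 to 12.5 ± 3.29 FPKM. Cd68 stood at 666 ± 20.9 FPKM in vehicle and 723 ± 62.2 FPKM in R (log2 change 0.11, SE 0.11), and Tyrobp at 671 ± 60 and 631 ± 85.1 FPKM (log2 change -0.09, SE 0.14). The list median was -0.49 (camera, adjusted p = 9.3e-07, or adjusted p = 0.32 with an estimated correlation), far smaller in size than those of the interferon and MHC lists. Aif1 and the fifth gene, Fcgr3, lost their calls without each library other than vehicle replicate 3 (adjusted p up to 0.082 and 0.091), and the value of Tyrobp was 0.02 without R replicate 3. Of 6 kept osteoclast markers 1 rose, the integrin Itgb3 (2.11 ± 0.546 to 5.86 ± 1.37 FPKM; list median 0.12; camera, adjusted p = 0.39), and its call ended without R replicate 3 (adjusted p = 0.051).

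Markers of other blood and vessel cells were low, and 6 lists had fewer than 5 kept members and were not tested as lists. Of the T and NK cell markers 3 were kept: Nkg7, a granule protein, fell from 2.22 ± 0.77 to 0.142 ± 0.126 FPKM (0 to 4 reads per R library), while Trbc2 (log2 change -1.02, adjusted p = 0.09, or adjusted p = 0.017 without R replicate 1) and Cd4 (log2 change 0.64, adjusted p = 0.24) did not pass. Of all 16 listed T and NK cell markers, most of them too low to be tested, 8 were lower in each R library than in each vehicle library and 1, Cd4, was higher. Of 11 listed endothelial markers, 7 were higher in each R library than in each vehicle library and 0 lower. Chance separates the groups in 10% of genes, counting both directions, and 29.3% of all kept genes were separated. Prf1, the pore-forming protein of killer cells, had 0 to 0.107 FPKM in R and 0.408 to 0.716 FPKM in vehicle, and the T cell co-receptor Cd8a had 0.122 to 0.202 and 0.508 to 1.41 FPKM. The endothelial adhesion gene Pecam1 had 0.366 to 0.664 FPKM in R and 0.189 to 0.216 FPKM in vehicle, and Emcn had 0.327 to 0.646 and 0.0975 to 0.185 FPKM. Of the neutrophil markers Csf3r and S100a8 were kept, of the B cell markers Ebf1, of the erythroid and megakaryocyte markers Epor and Pf4, of the endothelial markers Cdh5 and of the X and Y genes Xist, and 0 of these 7 passed limma's threshold over all genes, with 2 of them at an unadjusted p under 0.05. Only 2 of the 6 X and Y genes, Xist and Tsix, were in the deposited values, so that the Y-linked genes could not be assessed. The T and NK cell list had 2 falls and the endothelial list 1 rise, that of Cdh5, when adjusted over the list alone. The highest of the markers in these 6 lists was the platelet chemokine Pf4, also made by macrophages, at 116 ± 46 FPKM in vehicle and 75.7 ± 28.2 FPKM in R.

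MSC marker genes gave a mixed picture. Of 14 kept markers 0 rose and 1 fell over all genes: Ly6a (Sca-1), which interferon also induces, from 141 ± 59.3 to 23 ± 9.17 FPKM (log2 change -2.56, SE 0.41, adjusted p = 0.015), a call that ended without vehicle replicate 2 (adjusted p = 0.053). The list median was 0.44 (camera, adjusted p = 0.025, or adjusted p = 0.28 with an estimated correlation), with log2 changes of 0.95 for Cd200, 0.39 for Itgb1 and 1.7 for Mcam that did not pass. When adjusted over the list alone 7 rose and 1 fell, and the list call was lost without R replicate 3 (adjusted p = 0.11), with quantile normalization (0.052), with the stricter filter (0.051) and with fry (0.077). Of 19 haematopoietic niche factors 2 rose, Fgf2 and the pericyte proteoglycan Cspg4 (0.362 ± 0.164 to 3.02 ± 2.14 FPKM). The list was not past the threshold (median 0.2; camera, adjusted p = 0.11), though it passed without R replicate 1 (adjusted p = 0.0048) or vehicle replicate 2 (adjusted p = 0.02). Both rises also passed when adjusted over the list alone. The call of Cspg4 held without R replicate 1 and ended without any other library (adjusted p up to 0.15). Cspg4 was also the 1 rise among 5 smooth muscle and pericyte markers (median 1.34; camera, adjusted p = 0.078), where Acta2 stood at 248 ± 143 and 581 ± 162 FPKM (adjusted p = 0.1, or adjusted p = 0.037 without vehicle replicate 2). Adjusted over the list alone 3 of the 5 rose and 1 fell, and the list passed without R replicate 1 (adjusted p = 0.047) or vehicle replicate 2 (adjusted p = 0.02).

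Few lineage genes passed the threshold. Of 15 osteogenic genes 2 rose, the transcription factor Msx2 (1.27 ± 0.167 to 2.89 ± 0.569 FPKM) and the matrix protein Sparc (340 ± 110 to 707 ± 84.8 FPKM), and the list did not pass (median 0.21; camera, adjusted p = 0.078). Of 13 adipogenic genes 1 fell, the fatty acid transporter Cd36 (92.7 ± 16.8 to 50.6 ± 10.8 FPKM), while the list median was 0.27 (camera, adjusted p = 0.034, or adjusted p = 0.24 with an estimated correlation). The regulator Pparg stood at 14.4 ± 4.32 and 26.8 ± 4.74 FPKM (adjusted p = 0.053, or adjusted p = 0.023 without vehicle replicate 2). Adjusted over the list alone 3 osteogenic genes rose, and 1 adipogenic gene rose and 1 fell. The calls of Msx2 (up to 0.086), Sparc (up to 0.13) and Cd36 (up to 0.13) each ended without R replicate 2 or vehicle replicate 2, without vehicle replicate 1 for Msx2 and Cd36, without R replicate 3 for Sparc and Cd36 and without R replicate 1 for Sparc. The osteogenic list passed without R replicates 1 or 2 or vehicle replicates 2 or 3 (adjusted p = 0.031, 0.018, 0.032 and 0.033). The adipogenic list call was lost without R replicate 1, vehicle replicate 1 or vehicle replicate 3 (adjusted p = 0.056, 0.06 and 0.061), and with quantile normalization (0.081), equal medians (0.054), array weights (0.079) and fry (0.079). Of 5 chondrogenic genes 0 passed in limma over all genes or when adjusted over the list alone, with 2 at an unadjusted p under 0.05 (median 0.48; camera, adjusted p = 0.38). Of 16 WNT, NOTCH and BMP genes 1 rose, the NOTCH target Hes1, from 6.44 ± 1.5 to 18.6 ± 2.26 FPKM (list median 0.27; camera, adjusted p = 0.19), and 1 rose when adjusted over the list alone.

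Some matrix and TGF-beta response genes rose. Of 25 kept collagens and matrix proteins 6 rose and 0 fell, and 10 rose when adjusted over the list alone. Col5a2 rose from 45 ± 11.8 to 105 ± 21.2 FPKM, the basement membrane collagen genes Col4a1 and Col4a2 from 55.6 ± 17.6 and 40.2 ± 10.9 to 110 ± 8.26 and 81.9 ± 11.3 FPKM, and the matricellular protein Thbs1 from 255 ± 124 to 673 ± 102 FPKM. Not all moved up: the log2 changes were -0.21 (SE 0.37) for Col6a1 and -0.22 (SE 0.26) for Col3a1. Of 17 TGF-beta response and myofibroblast genes 6 rose and 0 fell, and 11 rose when adjusted over the list alone. Among them were Ccn2 (138 ± 34.4 to 330 ± 46.9 FPKM), Tpm1 (49.4 ± 6.74 to 79.5 ± 11.1 FPKM) and Smad7 (19.2 ± 4.08 to 31.6 ± 1.88 FPKM). The medians were 0.7 and 0.78 (camera, adjusted p = 8.3e-06 and 4.3e-06), and both calls were lost with an estimated correlation (adjusted p = 0.28 for each). With fry the matrix call was lost too (adjusted p = 0.077), while the TGF-beta call was kept (adjusted p = 0.046). The calls of single genes were less stable: without R replicate 1, 2 or 3 the matrix list held 1 rise each, and without vehicle replicate 1 it held 2, while it held 4 without vehicle replicate 2 or 3. The TGF-beta list held 2, 1 and 3 rises without R replicate 1, 2 and 3, 2 and 3 without vehicle replicates 1 and 2 and 4 without vehicle replicate 3. Of 16 matrix proteases and inhibitors 2 rose, Mmp11 among them, and 2 fell, the urokinase Plau (83.8 ± 14.6 to 39.2 ± 6.01 FPKM) and the collagenase Mmp13 (58.7 ± 35.9 to 14.9 ± 2.09 FPKM; median 0.14; camera, adjusted p = 0.31), and 5 rose and 2 fell when adjusted over the list alone. The calls of Mmp13 (up to 0.15) and Mmp11 (up to 0.1) ended without R replicates 1, 2 or 3 or vehicle replicate 1, and that of Mmp11 also without vehicle replicate 3. Both calls ended without a filter on low values, and that of Mmp13 (adjusted p = 0.0498) also as TPM, with quantile normalization, equal medians, array weights or a pseudocount of 5 and without the trend (adjusted p = 0.052 to 0.072).

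Cell cycle genes were lower in R by a small margin. Of 25 G2/M and mitosis genes 8 fell, among them the DNA topoisomerase Top2a (26.2 ± 1.43 to 16.1 ± 1.42 FPKM) and the checkpoint kinase Bub1 (8.57 ± 1.11 to 4.59 ± 0.847 FPKM). Of 23 G1/S and replication genes 7 fell, among them Mcm3 of the replicative helicase (36.3 ± 2.12 to 24.6 ± 2.86 FPKM) and Pcna, the sliding clamp of the DNA polymerases (120 ± 1.56 to 90 ± 5.16 FPKM). Adjusted over each list alone 15 fell in both, and 1 G1/S gene rose. The medians were -0.43 and -0.37 (camera, adjusted p = 4.8e-10 and 9.0e-08), and both calls were lost with an estimated correlation (adjusted p = 0.29 and 0.32). The G1/S falls numbered 0 without R replicate 1, R replicate 3, vehicle replicate 1 or vehicle replicate 2, and 1 without vehicle replicate 3. The G2/M falls, of which that of Top2a held throughout, numbered 1, 5, 3, 1, 2 and 2 without R replicates 1, 2 and 3 and vehicle replicates 1, 2 and 3. Of 6 replication-dependent histone genes 2 rose, Hist1h4h (3.74 ± 0.483 to 9.04 ± 1.63 FPKM) and Hist1h2bc (46 ± 3.78 to 73.8 ± 11.2 FPKM; median 0.62; camera, adjusted p = 4.3e-04, or adjusted p = 0.21 with an estimated correlation), and 5 rose when adjusted over the list alone. The call of Hist1h2bc ended without R replicate 1, R replicate 2 or vehicle replicates 1 or 2 (adjusted p up to 0.1).

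Apoptosis and inflammasome caspases fell. Of 20 apoptosis regulators 6 fell and 0 rose, led by Casp12 (4.15 ± 0.196 to 1.03 ± 0.136 FPKM), Casp4 (7.97 ± 0.581 to 2.73 ± 0.356 FPKM) and Casp1 (65.2 ± 6.55 to 29.4 ± 3.8 FPKM), of which Casp1 and Casp4 are caspases of the inflammasome. The list median was -0.28 (camera, adjusted p = 2.8e-06, or adjusted p = 0.21 with an estimated correlation), and 10 fell when adjusted over the list alone. Of 19 p53 target genes 1 rose, the death receptor Tnfrsf10b (5.79 ± 0.264 to 8.19 ± 0.84 FPKM; median 0.11; camera, adjusted p = 0.026, or adjusted p = 0.28 with an estimated correlation), 0 passed when adjusted over the list alone, and the call ended with any library left out (adjusted p up to 0.15). The p53 list call was lost without R replicate 2 (adjusted p = 0.069) or R replicate 3 (adjusted p = 0.079), with array weights (0.14) and with fry (0.073). The call of Tnfrsf10b also ended as TPM and without the trend or the filter (adjusted p = 0.052 to 0.1). Of 13 senescence genes 3 rose, Igfbp7 and Igfbp5 among them, and 1 fell, the lamin gene Lmnb1 (27.4 ± 0.641 to 18.4 ± 2.1 FPKM; median 0.04; camera, adjusted p = 0.19), and 5 rose and 1 fell when adjusted over the list alone. The 4 calls fell to 2, 2, 1, 1 and 2 without R replicates 1, 2 and 3 and vehicle replicates 1 and 2.

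Genes of glucose use were lower. Of 17 glycolysis genes 8 fell and 0 rose, and 14 fell when adjusted over the list alone. The lactate exporter Slc16a3 fell from 20 ± 4.89 to 6.07 ± 1.08 FPKM, Pgk1 from 322 ± 44.1 to 192 ± 12.3 FPKM and Pgam1 from 285 ± 3.38 to 203 ± 6.35 FPKM. The median was -0.48 (camera, adjusted p = 1.2e-08, or adjusted p = 0.19 with an estimated correlation). The falls numbered 2, 4, 3, 1 and 1 without R replicates 1, 2 and 3 and vehicle replicates 1 and 2. Of 15 hypoxia genes 2 fell, Pdk1 (10.8 ± 2.39 to 5.04 ± 0.536 FPKM) and Bnip3 (14.5 ± 3.25 to 7.3 ± 1.4 FPKM), and 3 fell when adjusted over the list alone. The list did not pass (median -0.06; camera, adjusted p = 0.083), though it did without vehicle replicate 3 (adjusted p = 0.023), and both gene calls ended without R replicate 1, R replicate 2 or vehicle replicates 1 or 2 (adjusted p up to 0.13). Of 13 mitochondrially encoded transcripts 4 rose, among them mt-Nd4 (609 ± 62.1 to 1000 ± 55.3 FPKM) and mt-Cytb (1760 ± 200 to 2810 ± 72.6 FPKM; median 0.49; camera, adjusted p = 7.6e-05, or adjusted p = 0.21 with an estimated correlation). Adjusted over the list alone 8 rose. The 4 calls all ended without R replicate 1, vehicle replicate 1 or vehicle replicate 2 (adjusted p up to 0.15), and 2 of them without R replicate 2 or 3. Nuclear copies of mitochondrial genes may take part of their reads. In 3 lists 0 genes passed limma's threshold over all genes or adjusted over the list alone. These were 27 nuclear-encoded oxidative phosphorylation genes (2 at an unadjusted p under 0.05; median -0.02; camera, adjusted p = 0.39), 20 cholesterol synthesis genes (3 at an unadjusted p under 0.05; median 0.04; camera, adjusted p = 0.39) and 22 cytosolic ribosomal protein genes (0 at an unadjusted p under 0.05; median -0.05; camera, adjusted p = 0.49). Without R replicate 2 the oxidative phosphorylation and ribosomal lists passed as lower (adjusted p = 0.0035 and 1.6e-04), and without R replicate 3 both medians were 0.04.

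Few stress response genes passed. Of 18 ATF4 and amino acid response genes 3 rose, Trib3 (4.45 ± 0.802 to 7.57 ± 1.12 FPKM), Chac1 (7.28 ± 1.72 to 14.2 ± 2.78 FPKM) and Atf5 (45.2 ± 10.5 to 79.3 ± 10.7 FPKM), with a list median of 0.15 (camera, adjusted p = 0.0012, or adjusted p = 0.32 with an estimated correlation). Of 15 NRF2 targets 2 rose, the quinone reductase Nqo1 (5.67 ± 0.906 to 20.7 ± 6.9 FPKM) and the haem oxygenase Hmox1 (438 ± 16.3 to 714 ± 72 FPKM; median 0.23; camera, adjusted p = 0.026, or adjusted p = 0.39 with an estimated correlation). Among the ATF4 genes 5 rose when adjusted over the list alone, and 5 NRF2 targets rose and 2 fell. Of 18 genes of the unfolded protein response 0 passed limma's threshold over all genes or adjusted over the list alone and 4 had an unadjusted p under 0.05, with a median of -0.14 (camera, adjusted p = 0.042, or adjusted p = 0.5 with an estimated correlation). The list calls were lost without R replicate 1 (adjusted p = 0.14), R replicate 3 (adjusted p = 0.063) or vehicle replicate 3 (adjusted p = 0.18) for the unfolded protein response and without vehicle replicate 2 (adjusted p = 0.077) for NRF2. With fry the ATF4, NRF2 and unfolded protein response calls were lost (adjusted p = 0.079, 0.079 and 0.11), with quantile normalization that of NRF2 (0.064), and with equal medians, the stricter filter or voom that of the unfolded protein response (0.066, 0.057 and 0.053). The unfolded protein response call was lost with the replicate block too. The calls of Atf5 and Chac1 ended as TPM (adjusted p = 0.051 for both). That of Atf5 also ended with array weights and without the trend, and that of Trib3 with the replicate block. Without the filter on low values the calls of Trib3, Chac1 and Atf5 all ended. The ATF4 gene calls numbered 1 without R replicate 1, 2 without vehicle replicate 3 and 0 without any other library (adjusted p up to 0.14). The call of Nqo1 ended without R replicate 2 (adjusted p = 0.0501) and that of Hmox1 without vehicle replicate 1 or 2 (adjusted p up to 0.069). In 3 further lists 1 gene each rose: Bag3 among 12 heat shock genes (33.7 ± 2.16 to 50.2 ± 3.91 FPKM), Nr4a1 among 18 immediate early genes (18.8 ± 4.68 to 42 ± 6.61 FPKM) and Map1lc3a among 22 autophagy and lysosome genes (31.5 ± 4.87 to 51.8 ± 3.97 FPKM). None of those 3 lists passed camera (adjusted p = 0.083, 0.058 and 0.37), and 1, 4 and 1 of their genes rose when adjusted over the list alone. The heat shock list passed without vehicle replicate 3 (adjusted p = 0.0049) and the immediate early list without R replicate 1, vehicle replicate 1 or vehicle replicate 2 (adjusted p = 0.049, 0.012 and 0.016). The calls of Bag3 (up to 0.075) and Map1lc3a (up to 0.071) ended without R replicate 1 or vehicle replicate 1, that of Map1lc3a also without R replicate 2 or vehicle replicate 2, and that of Nr4a1 (up to 0.075) without R replicates 2 or 3.

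Over the 38 lists, camera called 23, 9 higher and 14 lower in R, and in 0 of the 38 did the median, mean and camera direction differ in sign. With an estimated correlation 0 lists passed after adjustment (lowest adjusted p = 0.19) and 7 had an unadjusted p under 0.05, while fry called 16, 3 higher and 13 lower. Camera with an estimated correlation also has far fewer degrees of freedom, so these losses do not measure correlation between genes alone.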

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

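The limma-voom fit on recovered reads and the results for gene families were chosen after seeing the data, and all other alternatives were planned. The planned count tests of edgeR and DESeq2 were not run, because the values are FPKM and the recovered reads are estimates. Where a cause is not named below, the cause was not tested.

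The 809 genes past the threshold numbered 673 to 911 with the other pseudocounts, the stricter filter, the other scalings, limma without the trend, the replicate block and voom. The calls shared with each alternative had the same direction. The 344 genes without a filter on low values (65 higher, 279 lower) came from 25575 tested genes, and 17 lists were then higher. Array weights gave 2460 genes (1114 higher, 1346 lower). A pseudocount of 5 left 158 genes with a log2 change of at least 1 in size, since it shrinks changes at low values. Leaving out 1 library gave 337 to 879 genes, 63 to 352 higher and 272 to 527 lower. With an estimated correlation 0 lists passed (0 higher and 0 lower), and fry gave 3 higher. The gap between the median correlations within and between groups, 0.0243, was 0.0318 with a pseudocount of 0.1 and 0.1685 over the 1000 genes of largest variance. The scalings moved the median of all genes by at most 0.033 on the log2 scale.

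Of 4347 values of named genes under the alternatives, 3752 kept their direction and side of the threshold, 514 lost the call, 61 gained one and 20 changed sign. Of 719 list values, 637 were the same, 51 lost the call, 29 gained one and 2 changed sign. No result that changed sign had passed the threshold. Its value under each such setting follows, with the range over the left-out libraries. Socs6 was 0 as TPM and with voom, 0.03 with quantile normalization, equal medians and array weights, 0.05 without R replicate 2 and 0.03 without vehicle replicate 1 (-0.06 to 0.05). S100a8 was 0.02 with quantile normalization, 0.29 with array weights, 0.11 without R replicate 3 and 0.07 without vehicle replicate 1 (-0.18 to 0.11). Col2a1 was -1.46 with array weights and -0.42 without R replicate 3 (-0.42 to 1.69). Ebf1 was -0.4 with array weights, -0.11 without R replicate 3 and -0.07 without vehicle replicate 3 (-0.11 to 0.29). Col6a1 was 0.21 without R replicate 1 (-0.54 to 0.21). Socs7 (-0.13 to 0) and the chemokine receptors (-0.12 to 0) were 0 without R replicate 2. The oxidative phosphorylation (-0.11 to 0.04) and ribosomal (-0.18 to 0.04) lists were 0.04 and Tyrobp (-0.17 to 0.02) was 0.02 without R replicate 3, and Nfatc1 (-0.17 to 0.01) was 0.01 without vehicle replicate 3.

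No pairing of the samples by replicate number was seen, though with 3 libraries per group it cannot be excluded. Deviations from the group mean correlated at 0.14, -0.01 and -0.03 between libraries of the same number, across genes, and 2 of 6 libraries were closest to their own number. With the numbers as a block, 756 genes passed, of which 586 were among the 809, and 27 named results lost their call, among them Igfbp5 (adjusted p = 0.054), Pdlim1 (0.051), Thbs1 (0.052), Mcm3 (0.058), Pcna (0.065), Stat5a (0.075), Jak3 (0.081) and Bub1 (0.0502). At the estimated depths, 3 reads in a gene of 1 kb give 0.138 to 0.176 FPKM, and a longer gene has more reads at the same FPKM.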

Other observations

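All tests in this part were chosen after the result was seen, and so were the gene families. Some families of innate sensing that were not themselves fixed lists fell in R, in part or nearly as a whole. They can share members with the fixed lists, as Parp14 is also a listed interferon-stimulated gene. The PYHIN family, nucleic acid sensors of the Ifi200 cluster, had 7 of 8 kept members lower, among them Ifi204 (22.4 to 5.8 FPKM), and the Schlafen family 4 of 5, among them Slfn5 (17.3 to 3.8 FPKM). The PARP family had 5 of 12 lower, with Parp14 (17 to 3.3 FPKM), and 4 of 9 Toll-like receptors fell, Tlr4 among them (17.3 to 7.78 FPKM). Of 9 complement factors 3 fell, among them C3 (48.2 to 9.56 FPKM) and the C1 inhibitor gene Serping1 (43.4 to 13.5 FPKM). Camera gave an adjusted p of 1.1e-10, 1.8e-06, 1.1e-05, 2.2e-06 and 4.0e-07 for these 5 families, and with an estimated correlation these were 0.087, 0.087, 0.087, 0.15 and 0.087. The Toll-like receptor falls numbered 2 without R replicate 2, R replicate 3 or vehicle replicate 2.

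Other immune families had some lower members. In the TRIM family 8 of 34 fell, 1 rose and 25 did not pass (camera, adjusted p = 0.034, or 0.42 with an estimated correlation). The TRIM family call was also lost without R replicate 2 (adjusted p = 0.16), with array weights (0.071), without the filter on low values (0.07) and with a mean FPKM of at least 5 (0.24). Of 18 interleukin receptors 5 fell (adjusted p = 1.1e-04, or 0.1), of 12 C-type lectins 5 (2.3e-05, or 0.1) and of 7 Ms4a genes 3 (0.0026, or 0.18). Of 7 chemokine receptors 2 fell, and the family did not pass (median -0.1, adjusted p = 0.73). Of 4 Fc gamma receptors 3 fell, Fcgr4 among them (77.8 to 17.7 FPKM). The calls numbered 0 without R replicate 2, R replicate 3 or vehicle replicate 2 for the Ms4a genes and 3 without R replicates 2 or 3 or vehicle replicates 1 or 2 for the interleukin receptors. The C-type lectin calls numbered 1, 2, 2, 3 and 3 without R replicates 1, 2 and 3 and vehicle replicates 1 and 2, and the TRIM calls 5 without R replicate 2 or vehicle replicates 1 or 2.

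Some growth factor and cytoskeletal genes rose in R. Of 27 kept growth factor ligands 11 rose and 0 fell, with Bdnf (2.67 to 6.52 FPKM) and Hbegf (8.9 to 26.4 FPKM) called whichever library was left out. Of 31 actin-binding and focal adhesion genes 18 rose and 0 fell, among them Actn1 (66.2 to 117 FPKM) and the caveolar protein gene Cav1 (11.7 to 20.4 FPKM). Camera gave an adjusted p of 9.3e-06 and 2.2e-11, and 0.087 for both with an estimated correlation. Most of these calls were unstable. Without R replicates 1, 2 and 3 the growth factor rises numbered 6, 6 and 7 and the actin-binding and adhesion rises 6, 3 and 7. Without vehicle replicates 1, 2 and 3 they numbered 6, 5 and 11 and 3, 5 and 12. Of the 18 actin-binding and adhesion rises 2, Actn1 and Cav1, held in each of these fits, as did 5 of the 11 growth factor rises.

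Interferon-response and MHC genes were lower in R, with 76 of 78 kept genes past the threshold. Fewer macrophages in the R cultures are argued against as the whole cause, since these genes fell further than 21 macrophage markers (mean log2 changes of -2.3 and -0.59, difference -1.71, SE 0.05). Scaling is argued against by a median of -1.91 for the interferon-stimulated genes after quantile normalization. A fall of equal size in NF-kappaB targets, the only inflammatory list compared here, is argued against by the difference of -1.7 (SE 0.1) between those genes and that list. The mean log2 change was -2.07 for those genes and -0.37 for the NF-kappaB list. It was -1.04 for cytokines and chemokines, 2 of which are also in the interferon lists, and this list was not compared in the same way. Lower interferon signalling may explain the pattern, but it stays open which cells changed, whether reads shared between paralogs add to it, and whether fewer T and NK cells, a source of interferon-gamma, lie behind it, since 8 of their 16 markers were lower in each R library than in each vehicle library.

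Matrix and TGF-beta response genes were higher in R (41 genes, mean log2 change 0.65). A larger stromal share in the R cultures could give this, and it cannot be told apart from a change within stromal cells. The difference from 13 stromal markers (mean 0.42), without Ly6a because interferon induces it, was 0.23 with an SE of 0.19. With Ly6a, which fell by 2.56 on the log2 scale, the mean of the 14 markers was 0.21 and the difference 0.44 (SE 0.19), so that 1 gene decides whether the difference exceeds 2 SE.

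Macrophage markers were lower in R on average, but not alike. Their log2 changes had an SD of 0.67, which is 3.7 times their mean SE of 0.18. An equal loss of macrophages is thus argued against as the whole cause, and a changed macrophage state may contribute, while a smaller loss of cells stays open.

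Of the 10 splits of the 6 libraries into 3 and 3, the labelled one gave 809 genes past the threshold and the highest other gave 1, but 10 splits are too few for a share under 0.05.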
